A study of Drosophila melanogaster with 16 samples.

How the data were processed

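RNA from 5 dissected tissues at pupariation and about 18 h earlier was amplified and hybridised on 2-colour arrays, both times of a tissue on each array, per the labels. There were 16 arrays. Per the labels, replicate hybridisations used independent samples, and wing disc sample 1 was hybridised on 2 arrays, which were averaged here and counted as 1 replicate. The labels do not name separate animals or cultures, so p-values measure the spread between these samples.

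The deposited values are log2 ratios of the 2 dyes plus 1 additive constant per array. The log base was found from the values themselves, since after removal of the constant at least 99.95% of ratios below 30 were whole thousandths to within 0.01 on every array. The constant, the numerator, the background correction and the normalisation are not given in the sources used here. Medians over features of 1 named gene lay between -0.056 and 0.087 on the arrays as deposited. The top value of each array is 1 repeated number that corresponds to a ratio of 100000. It was treated as a placeholder and set to missing for 1853 values, 7 of them on features of 1 named gene. The table holds no intensities, so no filter on dim features, no bound for features near background and no intensity-dependent normalisation could be applied.

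The ratio was taken as Cy5 over Cy3, the order of the channels in the labels. In every array of the fit pupariation was in Cy5, so time and dye cannot be separated there. Nervous system replicate 2 was dye-swapped. A rule fixed before the data were examined turned its sign if its Pearson correlation over all features was negative with both other nervous system arrays, kept it if positive with both, and otherwise left it out. The Pearson r across features was -0.155 with replicate 3 and 0.024 with replicate 4, so it was left out. The Spearman rho was -0.233 and -0.029, by which its sign would have been turned, an alternative that was also run (39 genes called in the nervous system, against 7). Over features of 1 named gene r was -0.283 and -0.223, and 0.182 between replicates 3 and 4, and over features without a named gene it was -0.05 and 0.064. The fit thus held 14 replicates, where the plan had foreseen 15.

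Of 20000 features, 10827 carried 1 gene, 227 several and 8946 none in the platform annotation. Symbols were checked by gene identifier against a RefSeq gene table of assembly Release 6, used for names only, and 10823 matched, 4 did not and 0 symbols changed. No genome build is named for the array, so no coordinates are given. Features of one gene were averaged, giving 9904 genes, 793 of them with several features. Single features of those genes were called in opposite directions for 3 genes in epidermis, 1 in salivary gland and 0 in the other tissues. Some but not all features were called for 152 genes in epidermis, 146 in salivary gland, 13 in wing disc and 102 in midgut. All features were called alike for 76, 94, 1 and 63 genes in that order, so features of one gene often differed in being called.

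Each array was centred on its median. A gene was tested in a tissue where every replicate had a value. One limma fit (lmFit and eBayes, limma 3.58.1, R 4.3.3) over all replicates tested each tissue mean against 0, all tissues for differences (F-test) and each tissue against the mean of the other 4, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. Across genes, replicates correlated with a Pearson r of 0.602 to 0.63 in epidermis, 0.634 to 0.731 in salivary gland, 0.406 to 0.621 in wing disc, 0.569 to 0.644 in midgut and 0.205 in the nervous system, and the 2 arrays of wing disc sample 1 with 0.504. Genes changed in several tissues were set against 1000 permutations of genes within tissues. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

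Gene lists were written before the data were examined. They covered ecdysone-response regulators, glue proteins, Eig71E late genes, cell death, autophagy, digestive hydrolases, larval and pupal cuticle proteins, sclerotization and pigmentation, muscle sarcomere, disc morphogenesis, wing disc patterning, cell cycle and DNA replication, cytosolic ribosomal proteins, oxidative phosphorylation, proteasome, cytochrome P450, vacuolar ATPase, small heat shock proteins, antimicrobial peptides, markers of fat body, hemocytes, neurons, glia and neuroblasts, and ring gland steroidogenic genes. The cytochrome P450 list took every symbol that starts with Cyp and a digit, and so also holds the cyclophilin genes Cyp1 and Cyp40. Its counts, medians and tests include them where measured. The proteasome, ribosomal protein and oxidative phosphorylation lists were also filled by symbol prefix. They hold symbols of related genes such as Prosalpha4T1, RpL22-like and COX4L, so their shares and medians are not those of the core subunits alone. Of 26 lists, 25 had at least 4 genes with values in every replicate and entered camera, a competitive set test, with a preset correlation of 0.01. Adjustment ran over 125 tests. With that correlation 29 were called, and with an estimated correlation 1 was, muscle sarcomere in epidermis. The self-contained test fry, which asks whether a list moves on balance one way and compares it with no other genes, called 31.

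Named genes followed a rule fixed in advance. Per tissue they were the 6 largest rises and 6 largest falls past the threshold with one sign in all replicates, leaving out symbols that are only CG numbers unless fewer than 6 remained. To these came up to 3 members with the smallest p of each list with a call, the 10 smallest F-test p-values, the 3 largest differences in each direction per tissue, the genes changed alike in the most tissues, and the genes of the direction check.

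The fit was tested on simulated values with 200 changed genes per tissue. At a log2 change of 1 it recovered 55.3% in epidermis, 59% in salivary gland, 48% in wing disc, 50% in midgut and 45.7% in the nervous system, and at a change of 2 it recovered 91.4%, 96%, 89.9%, 95.9% and 90%. False calls made up 3.4% to 6.1% of calls. The simulation drew independent normal noise with 1 spread per gene in all tissues. In the data the median replicate SD ran from 0.222 in wing disc to 0.384 in salivary gland among the tissues with 3 replicates. The 0.201 of the nervous system came from 2 replicates and is not on the same scale, as a median SD depends on their number. Genes may also vary together. These rates therefore need not hold for the data.

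Alternatives fixed in advance were no centring, scaling of arrays, single features, fewer required values, a separate fit per tissue, array weights, a robust prior, a minimum change, the replicate number as a block, either array of wing disc sample 1, a dye term and each replicate left out. Both signs of the dye-swapped array were added after the data had been seen.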

Results

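The series compared gene expression in 5 tissues of Drosophila melanogaster larvae (Canton S strain) at pupariation, when the larva becomes a prepupa, with the same tissue about 18 h earlier. The tissues were epidermis with its attached muscle, salivary gland, wing disc, midgut and central nervous system. Both times of one tissue were hybridised in different dyes on 1 array, and 16 arrays were deposited. Each value is therefore a within-array ratio, given here as log2 of pupariation over the earlier time. That direction is likely rather than settled, because the labels name the dye of each time but not the numerator. With the other dye as numerator every sign below turns, so that the largest rises become the largest falls and shares higher become shares lower. The comparison used 3 replicates of epidermis, salivary gland, wing disc and midgut and 2 of the nervous system. Each array held values for 10169 to 10825 features of 1 named gene. The number of arrays limits the precision, and values are means ± SD over replicates.

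In the epidermis with muscle, the largest rise was 7.48 and the largest fall -6.05, both of genes whose symbols are only CG numbers. Among other symbols, the tyrosine hydroxylase gene ple rose most, by 5.56 ± 0.11 in log2 ratio (n = 3, 47.2-fold, adjusted p = 1.25e-08). The beta-alanyl-dopamine synthase gene e rose by 5.54 ± 0.79, and the dopamine N-acetyltransferase gene speck rose by 5.52 ± 1.02. The serpin Spn100A rose by 5.52 ± 1.30, the insulin-like peptide gene Ilp8 by 4.75 ± 0.47 and Esp by 4.51 ± 0.45. Among symbols other than CG numbers, the largest falls were in the alkaline phosphatase gene Alp1 (-5.14 ± 0.61), the cuticle protein gene Cpr67B (-5.05 ± 0.49) and the chitin-binding protein gene obst-E (-5.03 ± 1.22). Values for yellow-d2, Pxd and l(3)mbn were -4.95 ± 0.17, -4.94 ± 1.36 and -4.58 ± 2.53, all past the threshold.

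Of 9308 genes tested in epidermis, 1652 changed (17.7%), 694 higher and 958 lower at pupariation, and 2844 had an unadjusted p under 0.05. The count was 1046 without epidermis replicate 3, 651 when each tissue was fitted alone and 937 with an absolute log2 ratio of at least 1.

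Muscle sarcomere genes fell as a group in epidermis. Of 18 measured, 14 fell and none rose, with a median of -1.74 (adjusted p = 1.04e-11, and 0.0419 with an estimated correlation). Adjusted over the list alone, 15 were lower and 1 higher. The regulatory light chain gene Mlc2 was at -4.21 ± 0.45, tropomyosin 2 (Tm2) at -3.30 ± 0.14 and troponin T (up) at -2.04 ± 0.32. Of 7 markers of hemocytes, the blood cells, 3 fell in epidermis (Hml -2.81 ± 2.06, Col4a1 -1.52 ± 0.67, Pxn -1.30 ± 0.99). Their median was -1.18, 4 were lower when adjusted over the list alone, and the list test gave an adjusted p of 0.124. Markers of fat body, the larval storage tissue, had a median of 1.14 there, with 2 of 6 higher (Fbp2 2.77 ± 0.09, Fbp1 2.13 ± 1.08), 3 when adjusted over the list alone, and an adjusted p of 0.119. The Fbp1 call was lost without epidermis replicate 1 or 2 (adjusted p = 0.0699 and 0.0531), and the Pxn call without replicate 3 (0.0809).

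Genes of sclerotization and pigmentation moved both ways in epidermis, with 4 of 20 higher and 7 lower, or 4 and 9 adjusted over the list alone. Their median was -0.22 and their mean -0.14, while the set test pointed up (adjusted p = 0.688). Of 6 measured larval cuticle protein genes 1 rose (Lcp65Ad, 0.73 ± 0.31) and 1 fell (Lcp9, -3.27 ± 1.64), with an adjusted p of 0.785 for the list. Of 12 pupal cuticle protein genes 1 rose (Ccp84Ag, 2.40 ± 1.23) and 2 fell (Pcp, -2.41 ± 0.44, and Ccp84Ad, -1.63 ± 1.95), with an adjusted p of 0.335, and 3 were lower when adjusted over the list alone. Regulators of the ecdysone response had 3 of 15 higher and 3 lower in epidermis (4 lower when adjusted over the list alone), with EcR at -2.29 ± 1.44, or -1.46 without epidermis replicate 3. Their median was 0.11 and their mean -0.10, and the set test pointed up (adjusted p = 0.81). Leaving out 1 epidermis replicate ended the calls of Lcp65Ad (adjusted p = 0.134 without 1 and 0.0772 without 2), Ccp84Ag (0.0959 without 3) and Ccp84Ad (0.324 without 2, at -0.53, and 0.0556 without 3).

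Small heat shock protein genes had a median of 1.90 in epidermis, with 4 of 5 higher and 1 lower (adjusted p = 0.00787, and 0.601 as the adjusted p with an estimated correlation). CG4456, on the list only through its older name Hsp67Bb, was at 2.34 ± 0.44 and Hsp27 at 2.28 ± 0.33, whereas l(2)efl was at -2.40 ± 0.64. Proteasome genes had a median of 0.58, with 9 of 37 higher, among them Rpn3 at 0.94 ± 0.18 (adjusted p = 1.59e-06, and an adjusted p of 0.617 with an estimated correlation). Genes of the vacuolar ATPase, the proton pump of acidic organelles, had a median of -0.78 and 12 of 23 were lower, including VhaAC45 at -1.57 ± 0.36 (adjusted p = 0.000414, and an adjusted p of 0.601 with an estimated correlation). Digestive hydrolase genes had a median of -1.30 with 9 of 34 lower, including Jon25Biii at -2.97 ± 0.81 (adjusted p = 1.17e-05, and an adjusted p of 0.617 with an estimated correlation). The cytochrome P450 list, which also holds the cyclophilin genes Cyp1 and Cyp40, had 15 of 66 lower and 1 higher, with Cyp12e1 at -2.03 ± 0.11 (adjusted p = 0.00787, and an adjusted p of 0.617 with an estimated correlation). Oxidative phosphorylation genes had 13 of 60 lower and 2 higher, with ATPsyngamma at -0.96 ± 0.28 (adjusted p = 0.00503, and an adjusted p of 0.779 with an estimated correlation). That list call was lost without epidermis replicate 1 (adjusted p = 0.0752) or 2 (0.212). Cytosolic ribosomal protein genes had a median of 0.19 and 2 of 36 higher (adjusted p = 0.0426, and an adjusted p of 0.852 with an estimated correlation). The ribosomal median was 0.31, 0.29 and -0.03 without epidermis replicate 1, 2 and 3, with an adjusted p of 0.894 without 3. Without replicate 3 the medians of digestive hydrolases and proteasome were -0.44 and 0.38, both lists still called. Adjusted over the list alone, 16 proteasome genes were higher, 10 digestive hydrolase genes lower, 22 cytochrome P450 genes lower and 2 higher, and 17 oxidative phosphorylation genes lower and 3 higher, while the other 3 lists of this paragraph kept their counts.

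**Figure D1:**
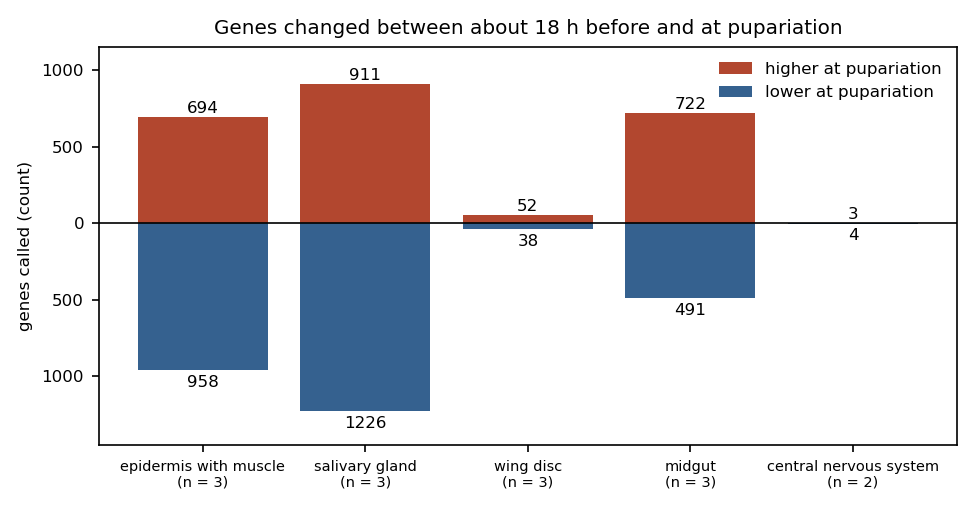
Number of genes called in each tissue at an adjusted p under 0.05, with genes higher at pupariation above the zero line and lower ones below it, and n the number of replicates. Salivary gland had 911 higher and 1226 lower, and the nervous system 3 and 4.

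In the salivary gland, genes of the glue that fixes the animal to its substrate fell. All 4 measured glue genes fell, with Sgs5 at -4.78 ± 0.39, ng3 at -4.72 ± 0.30, Sgs1 at -4.01 ± 1.02 and Sgs5bis at -3.09 ± 0.95 (n = 3). Sgs5bis is named because it completes that count, after its value was seen. The list had no set test, which needed 4 genes with values in every replicate, since 3 were measured in the nervous system. The zinc transporter family genes Zip99C and ZnT86D rose by 5.97 ± 0.71 (62.8-fold) and 5.30 ± 0.83, while Zip88E fell by 4.46 ± 0.55. The sulfhydryl oxidase gene Qsox1 rose by 5.80 ± 0.66, the glutaminyl cyclase gene isoQC by 5.53 ± 0.55, the peptidoglycan recognition protein gene PGRP-SB2 by 5.49 ± 0.77 and Miga by 5.41 ± 0.18. Muc68Ca, a mucin gene, fell by 4.20 ± 1.10.

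Of 9862 genes tested in salivary gland, 2137 changed (21.7%), 911 higher and 1226 lower, and 3076 had an unadjusted p under 0.05. With an absolute log2 ratio of at least 1 the count was 1116.

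The Eig71E late genes, a cluster known to respond to the steroid hormone ecdysone, had a median of 2.81 in salivary gland. Of 9 measured, 7 rose, including Eig71Ek (2.84 ± 0.48) and Eig71Eh (2.75 ± 0.33), and Eig71Ee fell by 4.31 ± 0.39. Adjusted over the list alone, 8 were higher and 1 lower. The list had an adjusted p of 8.71e-06, and an adjusted p of 0.199 with an estimated correlation. Autophagy genes had 8 of 21 higher and none lower, with Atg2 at 1.91 ± 0.57 and Atg7 at 1.54 ± 0.52 (adjusted p = 0.000246, and an adjusted p of 0.601 with an estimated correlation). Cell death genes had 4 of 15 higher, including Buffy at 2.50 ± 0.91 and Dark at 1.64 ± 0.63, and the list had an adjusted p of 0.159. Among regulators of the ecdysone response 5 of 15 rose and 3 fell, 6 and 3 adjusted over the list alone, with Eip63E at 3.5 ± 0.36, the ABC transporter gene E23 at 1.69 ± 0.65 and the nuclear receptor gene Hr39 at 1.64 ± 0.70 (adjusted p = 0.104). Of 5 antimicrobial peptide genes 3 rose (Def 1.6 ± 0.90, AttB 1.4 ± 1.69, AttD 0.89 ± 0.65) and the list had an adjusted p of 0.25. The AttB and AttD calls were lost without salivary gland replicate 1 (adjusted p = 0.315 and 0.348) or 2 (0.198 and 0.0861), with AttB at 0.80 and AttD at 0.54 without 1 and AttB at 2.37 without 4. Of 9 neuroblast marker genes, insc (0.75 ± 0.22) and Imp (0.84 ± 0.56) rose (list adjusted p = 0.263), and the Imp call was lost without replicate 4 (0.53, adjusted p = 0.0914).

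Cell cycle and DNA replication genes had 9 of 22 lower in salivary gland, with a median of -0.38, PCNA at -1.78 ± 0.28 and Mcm6 at -1.52 ± 0.22 (adjusted p = 0.00418, and an adjusted p of 0.617 with an estimated correlation). Oxidative phosphorylation genes had 14 of 61 lower, with ATPsynE at -1.56 ± 0.65 (adjusted p = 0.00188, and an adjusted p of 0.749 with an estimated correlation). Vacuolar ATPase genes had 9 of 24 lower and 1 higher, Vha100-1 at 1.39 ± 0.63 (adjusted p = 0.0178, and an adjusted p of 0.617 with an estimated correlation). That list call was lost without salivary gland replicate 4 (adjusted p = 0.129). Ribosomal protein genes had a median of 0.30 and 4 of 37 higher, including RpL15 at 1.12 ± 0.58 (adjusted p = 0.0132, and an adjusted p of 0.788 with an estimated correlation), a list call lost without salivary gland replicate 1 (median 0.07, adjusted p = 0.312), with a median of 0.47 without 4. Adjusted over the list alone, 10 cell cycle genes were lower and 1 higher, 11 vacuolar ATPase genes lower and 1 higher, and 1 ribosomal protein gene higher, while the oxidative phosphorylation count stayed at 14. Proteasome genes had 4 of 37 lower and none higher in salivary gland (1 lower adjusted over the list alone), with a median of -0.07 (adjusted p = 0.916). They differed downward from the other tissues with an adjusted p of 0.000752, and an adjusted p of 0.707 with an estimated correlation. Cytochrome P450 genes had 9 of 79 higher and 8 lower there (10 and 11 adjusted over the list alone), with an adjusted p of 0.787.

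In the wing disc, 3 of 15 measured disc morphogenesis genes rose, also when adjusted over the list alone (adjusted p = 0.00254, and an adjusted p of 0.416 with an estimated correlation). They were the ecdysone-inducible genes ImpE3 (2.56 ± 0.37), ImpE2 (2.07 ± 0.27) and ImpE1 (1.21 ± 0.17, n = 3). The ImpE1 call ended without wing disc replicate 1, 2 or 3 (adjusted p = 0.311, 0.214 and 0.512), and that of ImpE2 without 1 or 3 (0.0963 and 0.0718). Spn100A rose by 3.01 ± 0.58 (8.03-fold), the RNA-binding protein gene sm by 2.51 ± 0.47, the transcription factor gene Blimp-1 by 2.35 ± 0.91 and the sulfotransferase gene St2 by 2.27 ± 0.36. The chitinase-like Idgf6 fell by 2.39 ± 0.53, the cuticle protein gene Cpr51A by 2.38 ± 0.38, Osi2 by 1.51 ± 0.59, the protease gene tld by 1.37 ± 0.30, the collagen gene Col4a1 by 1.30 ± 0.44 and the kinesin gene ncd by 1.27 ± 0.38.

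Of 9892 genes tested in wing disc, 90 changed (0.91%), 52 higher and 38 lower, and 898 had an unadjusted p under 0.05. The count depended on the handling of arrays. It was 856 with array weights, 586 with arrays scaled to one median absolute deviation (44% of them higher, against 57.8%), 49 when fitted alone, and 15, 25 and 14 without wing disc replicates 1, 2 and 3. Leaving out any wing disc replicate ended the calls of Osi2, Col4a1, ncd, Mcm2 and Mcm5 (highest adjusted p = 0.509, 0.437, 0.321, 0.236 and 0.318), and some ended those of Cpr51A (0.0861 without 1 and 0.0551 without 2), Spn100A (0.0593 without 3) and tld (0.0746 without 1).

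Cell cycle and DNA replication genes had a median of -0.52 in wing disc. Mcm2 (-1.2 ± 0.09) and Mcm5 (-1.2 ± 0.15), subunits of the replicative helicase, were called of 22 measured, and 12 were lower when adjusted over the list alone. The list had an adjusted p of 3.88e-14, and an adjusted p of 0.125 with an estimated correlation. Fat body markers had a median of 0.98 with 0 of 6 called by limma and 1 at an unadjusted p under 0.05 (adjusted p = 0.0178, and an adjusted p of 0.601 with an estimated correlation), and without wing disc replicate 1 their median was 0.25 and their adjusted p 0.188. Ribosomal protein genes had a median of -0.21 with 0 of 37 called by limma and 5 at an unadjusted p under 0.05 (adjusted p = 0.00849, and an adjusted p of 0.779 with an estimated correlation). Wing disc patterning genes had a median of -0.19 with 0 of 17 called by limma and 3 at an unadjusted p under 0.05 (list adjusted p = 0.25).

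**Figure D2:**
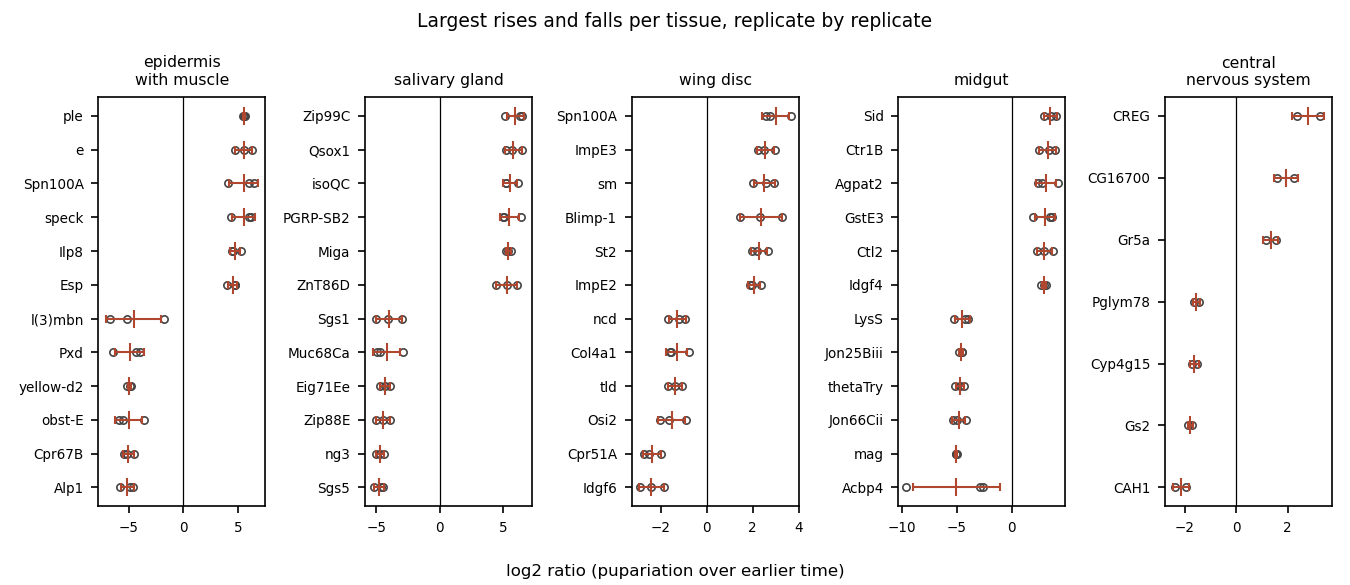
Log2 ratio (x axis) of the genes named for the largest rises and falls in each tissue, symbols that are only CG numbers left out where 6 others remained, with circles for single replicates and red bars for the mean ± SD over 3 replicates, or 2 in the nervous system. The ple circles of epidermis lie close together (SD 0.11), and those of Acbp4 in midgut spread widely (SD 3.97).

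In the midgut, genes of digestive enzymes fell. Of 41 measured digestive hydrolase genes 32 fell and 1 rose, LysX (1.05 ± 0.20, named after its value was seen), with a median of -3.13 (adjusted p = 1.91e-19, and an adjusted p of 0.392 with an estimated correlation), and adjusted over the list alone 36 were lower and 1 higher. The lipase gene mag fell by 5.04 ± 0.08 (n = 3, 32.8-fold), and the protease genes Jon66Cii (-4.84 ± 0.61), thetaTry (-4.73 ± 0.37) and Jon25Biii (-4.64 ± 0.16) and the lysozyme gene LysS (-4.48 ± 0.66) fell as well. The acyl-CoA-binding protein gene Acbp4 was at -5.05 ± 3.97, and at -2.76 without replicate 3, still past the threshold. The largest rise in midgut was 4.24, of a gene whose symbol is only a CG number. Among other symbols Sid rose by 3.52 ± 0.59, the copper transporter gene Ctr1B by 3.27 ± 0.76, the acyltransferase gene Agpat2 by 3.13 ± 0.94, the glutathione transferase gene GstE3 by 3.03 ± 0.92, Ctl2 by 2.99 ± 0.71 and Idgf4 by 2.93 ± 0.21.

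Of 9497 genes tested in midgut, 1213 changed (12.8%), 722 higher and 491 lower, and 2215 had an unadjusted p under 0.05. The count was 575 without midgut replicate 3, 701 when fitted alone and 749 with an absolute log2 ratio of at least 1.

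Proteasome genes had a median of 1.03 in midgut, with 25 of 37 higher and none lower, including Prosalpha5 at 1.63 ± 0.33 and Rpn3 at 1.58 ± 0.20 (adjusted p = 2.84e-13, and an adjusted p of 0.536 with an estimated correlation). Autophagy genes had 5 of 21 higher, including Atg2 at 1.43 ± 0.05 (adjusted p = 0.00849, and an adjusted p of 0.617 with an estimated correlation). The ecdysone-response transcription factor gene Eip93F rose by 2.74 ± 0.40. Cytochrome P450 genes had 19 of 73 lower and 1 higher, with Cyp304a1 at -3.46 ± 0.76 (adjusted p = 0.000236, and an adjusted p of 0.601 with an estimated correlation). Vacuolar ATPase genes had 8 of 24 lower, with Vha100-4 at -1.68 ± 0.86 (adjusted p = 0.000414, and an adjusted p of 0.601 with an estimated correlation). Muscle sarcomere genes had 4 of 17 lower, with Mlc2 at -1.83 ± 0.67 and Tm2 at -0.93 ± 0.34 (adjusted p = 0.0178, and an adjusted p of 0.601 with an estimated correlation). Npc1a, a sterol transport gene of the ring gland list, rose in epidermis (1.06 ± 0.17), salivary gland (0.76 ± 0.63) and midgut (1.26 ± 0.22), and that list had a median of -0.26, a mean of 0.03 and a set test that pointed up in midgut (adjusted p = 0.81). The Npc1a call in salivary gland was lost without its replicate 1 or 2 (adjusted p = 0.166 and 0.13). Adjusted over the list alone, 26 proteasome genes were higher and 1 lower, 9 autophagy genes higher, 23 cytochrome P450 genes lower and 1 higher, 12 vacuolar ATPase genes lower, and 8 muscle genes lower and 2 higher.

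In the central nervous system 7 of 9319 genes changed (0.0751%), 3 higher and 4 lower, and 759 had an unadjusted p under 0.05. CREG rose by 2.82 ± 0.62 (n = 2, 7.05-fold), CG16700 by 1.94 ± 0.47 and the gustatory receptor gene Gr5a by 1.34 ± 0.28. The carbonic anhydrase gene CAH1 fell by 2.17 ± 0.31, the glutamine synthetase gene Gs2 by 1.80 ± 0.10, the cytochrome P450 gene Cyp4g15 by 1.63 ± 0.16 and the phosphoglycerate mutase gene Pglym78 by 1.55 ± 0.13. The dye-swapped array was left out of this fit. With its sign turned to match the others, it gave the same signs for all 7 genes (CREG 3.07, CG16700 2.64, Gr5a 0.93, CAH1 -2.15, Gs2 -1.75, Cyp4g15 -1.50, Pglym78 -1.25).

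The nervous system count rested on single arrays. It was 0 by limma without nervous system replicate 3, with 75 genes at an unadjusted p under 0.05, and 508 without replicate 4, and 3, 1, 1 and 1 without salivary gland replicate 2, wing disc replicate 1, wing disc replicate 2 and midgut replicate 1. It was 39 with the dye-swapped array turned, 29 with a dye term, 218 with arrays scaled (33% higher, against 42.9%), 23 with array weights, 0 when fitted alone (364 unadjusted) and 0 with the dye-swapped array as deposited (268 unadjusted).

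In the nervous system, Gs2 was the 1 called gene of 7 glial markers (list adjusted p = 0.25). Of 9 neuroblast markers 0 were called by limma and 0 had an unadjusted p under 0.05 (list adjusted p = 0.597), and of 5 ring gland genes 0 were called and 3 had an unadjusted p under 0.05 (median -0.42, list adjusted p = 0.905). Neuronal markers had a median of -0.17 with 0 of 14 called and 3 at an unadjusted p under 0.05 (adjusted p = 0.039, and an adjusted p of 0.601 with an estimated correlation), and the list call was lost without either replicate (adjusted p = 0.142 without 3, with a median of -0.09, and 0.1 without 4). Disc morphogenesis genes had a median of 0.19 with 0 of 15 called, 3 higher when adjusted over the list alone and 4 at an unadjusted p under 0.05 (adjusted p = 0.000301, and an adjusted p of 0.295 with an estimated correlation), and the median was 0.32 without replicate 4. Cytochrome P450 genes had a median of -0.27 with 1 of 70 lower (adjusted p = 0.0147, and an adjusted p of 0.617 with an estimated correlation). Proteasome genes had a median of 0.17 with 0 of 35 called and 1 at an unadjusted p under 0.05 (adjusted p = 0.0228, and an adjusted p of 0.779 with an estimated correlation). The P450 and proteasome calls were lost without replicate 3 (medians -0.01 and 0.01, adjusted p = 0.974 and 0.716), and the medians were -0.45 and 0.38 without 4. Ribosomal protein genes had a median of -0.20 with 0 of 37 called and 3 at an unadjusted p under 0.05 (adjusted p = 0.00909, and an adjusted p of 0.779 with an estimated correlation), and the call was lost without replicate 4 (median -0.07, adjusted p = 0.661), with a median of -0.31 without 3.

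**Figure D3:**
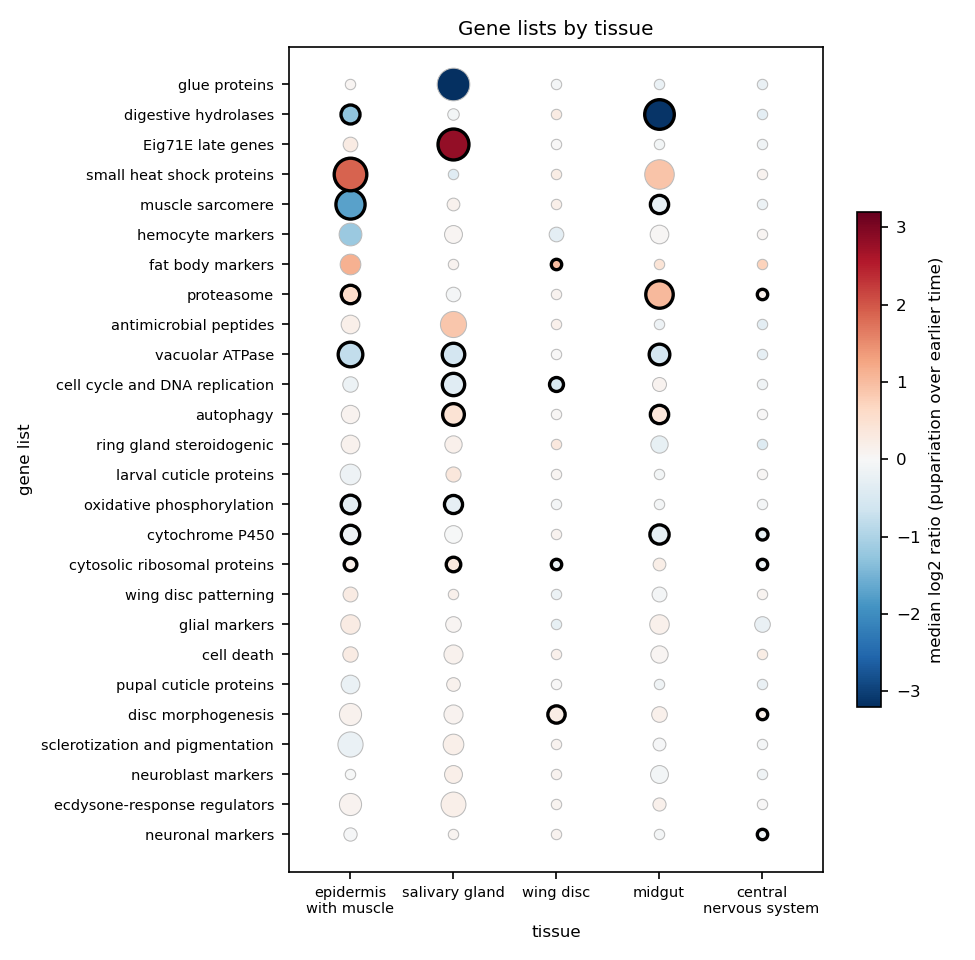
Gene lists (rows) in the 5 tissues (columns), with colour for the median log2 ratio of measured members, circle size for the share of members called in either direction, and black rims for lists called with the preset correlation. Digestive hydrolases in midgut (median -3.13) and Eig71E late genes in salivary gland (2.81) have the strongest colours among rimmed circles.

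The change between times differed between tissues for 2064 of 8698 genes with values in every replicate (23.7%, limma F-test). The transferrin family gene Tsf3 had an F of 257, with 5.21 in salivary gland and -1.58 in epidermis, and Miga an F of 254, with 5.41 in salivary gland and 0.08 in epidermis. Next came isoQC, Qsox1, anchor, CG1213, CG11349, yellow-d2, Zip99C and Pex3. For CG11349 and yellow-d2 the value lay furthest from 0 in epidermis (-4.70 and -4.95), and CG1213 was at 5.39 there and 1.55 in salivary gland.

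Against the mean of the other tissues, 826 genes differed in epidermis, 1459 in salivary gland, 396 in wing disc, 974 in midgut and 48 in the nervous system. In epidermis speck lay 5.32 above the others and Pxd differed by -4.98. In salivary gland Qsox1 differed by 6.09 and ng3 by -4.68. In wing disc the arginine kinase gene Argk1 differed by 2.24, with 0.50 there and a mean of -1.74 elsewhere, and CREG by -3.33, with -0.24 there and 3.10 elsewhere. In midgut GstE3 differed by 3.69 and PGRP-SC2 by -3.98. In the nervous system Cyp4ac1 differed by 1.61 and the lysosomal mannosidase gene LManI by -2.87. Leaving out 1 replicate moved the epidermis count to 540 (without its replicate 3) and the midgut count to 454 (without its replicate 3). The wing disc count was 105, 130 and 60 without its replicates 1, 2 and 3, 615 without salivary gland replicate 4 and 250 without nervous system replicate 3. The nervous system count was 0 by limma without its replicate 3 (339 at an unadjusted p under 0.05) and 383 without its replicate 4, 84 without salivary gland replicate 4, and 21, 20 and 26 without wing disc replicates 1, 2 and 3. With array weights and with arrays scaled the wing disc count was 1437 and 771, and the nervous system count 149 and 147. The nervous system count was 108 with a dye term, and 200 and 177 with the dye-swapped array turned and as deposited. With an absolute log2 ratio of at least 1 the salivary gland count was 893 and the midgut count 608. The differences of Cyp4ac1 and LManI had an adjusted p of 0.611 and 0.71 without nervous system replicate 3, and that of Cyp4ac1 one of 0.0699 with a dye term. With the dye-swapped array as deposited CREG in wing disc had an adjusted p of 0.0838.

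Muscle sarcomere genes differed between epidermis and the other tissues as a list (adjusted p = 4.45e-14, and an adjusted p of 0.0197 with an estimated correlation). This was 1 of 33 list differences called with the preset correlation and the only one called with the estimated correlation, of 125 tests.

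More genes changed alike in several tissues than independent lists give. Of 8698 genes tested in every tissue, 192 changed in the same direction in at least 3 tissues, 149 higher and 43 lower, against 13.2 for independent lists and at most 26 in 1000 permutations. The count was 112 without midgut replicate 3, 81 when tissues were fitted alone and 91 with an absolute log2 ratio of at least 1. CREG and Gr5a rose in epidermis (3.65 and 1.73), salivary gland (3.72 and 3.07), midgut (2.19 and 1.69) and nervous system (2.82 and 1.34). Pglym78 fell in the same 4 tissues (-2.29, -2.54, -0.70 and -1.55). The chitinase gene Cht5, CG4586, catalase (Cat) and CatB rose, and Sqor fell, in epidermis, salivary gland, wing disc and midgut. Cht5 was at 3.24, 1.46, 1.13 and 2.25 in that order, and Sqor at -0.70, -0.86, -0.97 and -0.67. Several of these calls ended with 1 replicate left out. In wing disc this held for Cht5, Cat, CatB and Sqor without any of the 3 (highest adjusted p = 0.458, 0.395, 0.207 and 0.472) and for CG4586 without 1 or 3 (0.0714 and 0.111). In epidermis it held for Cat without any (0.143) and Sqor without 2 or 3 (0.153 and 0.0989), in salivary gland for Sqor without 1 (0.051), in midgut for Cat without 3 (0.198), Sqor without 1 or 3 (0.114 and 0.445, the latter at -0.41) and Pglym78 without 1 or 3 (0.111 and 0.246), and in the nervous system for CREG, Gr5a and Pglym78 without 3 (1, 1 and 0.941). A further 232 genes were higher in one tissue and lower in another, against 403 for independent lists. Across genes, which are not independent replicates, epidermis and salivary gland had a Pearson r of 0.335, and wing disc and midgut -0.015.

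Of the genes named in advance to check the direction of the ratio, Hr3 and Eip78C were measured, and Sgs3, Sgs7, Sgs8, Eip75B, Eip74EF and Eip63F-1 were not analysed here. Hr3, an ecdysone-induced nuclear receptor gene, was above 0 in 5 of 5 tissues and passed the threshold in epidermis (1.45 ± 1.2) and salivary gland (2.07 ± 1.06). The epidermis call was lost without replicate 2 or 3 (adjusted p = 0.178 and 0.308), and the salivary gland call without replicate 1 (0.0648). Eip78C passed it in none, with values from -0.44 ± 0.84 in midgut to 0.45 ± 0.09 in salivary gland.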

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

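The tests chosen only after their results had been seen were the 2 of dye bias, on muscle genes and on genes changed in several tissues, and the 2 on the low count in wing disc. For the 2 tests of dye bias, the bound that would have counted against it was tightened after the values were known, and under the earlier bound both values counted against dye bias.

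The fall of muscle sarcomere genes in epidermis with muscle (median -1.74, 14 of 18 lower) may reflect a smaller share of muscle in the later sample. Muscle genes outside that list had a median of -1.44 (standard error 0.66, 7 measured of 10 written beforehand). Of these, SERCA (-2.31), RyR (-2.12), Msp300 (-1.44) and Argk1 (-3.66) fell, while Strn-Mlck (0.07), Ca-alpha1D (-0.17) and rhea (-0.21) were not called. Argk1 was also called lower in salivary gland and midgut, so its fall was not confined to epidermis with muscle. A fall in transcription within the muscle would look like a smaller share of muscle. A gene-specific dye bias would also lower the list in other tissues with the same dyes, and the medians were 0.14 (standard error 0.11) in salivary gland and 0.18 (0.08) in wing disc, but -0.28 in midgut, with 4 of 17 lower (adjusted p = 0.0178, and 0.601 with an estimated correlation), and -0.20 in the nervous system. Dye bias therefore stays open, also because limma called 1 and 0 of 18 in salivary gland and wing disc (1 in wing disc at an unadjusted p under 0.05) and unexpressed genes show no ratio. Camera called the list different between epidermis and the other tissues (adjusted p = 4.45e-14, and 0.0197 with an estimated correlation). Whether that difference is a change of expression specific to this tissue was not tested and stays open too.

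The 192 genes that changed in one direction in at least 3 tissues were more than independent lists give, since 0 of 1000 permutations of genes reached that count and the highest gave 26, although the count dropped to 112 without midgut replicate 3. The permutations treated all genes as equally easy to call, which 1 spread per gene over all tissues does not ensure. Genes higher in one tissue and lower in another numbered 232, fewer than the 403 of independent lists. A gene-specific dye bias could still produce such sharing, because pupariation was in Cy5 on every array fitted. On the dye-swapped nervous system array as deposited, the median of their signed values was -0.344 (standard error 0.0487), and 151 of 192 turned with the dyes. On the unswapped nervous system replicates 3 and 4, 167 and 159 of 192 kept the sign they had elsewhere. A sign that turns with the dyes would come from a change between times rather than from dye bias. Because only 1 array was swapped, dye bias is still not excluded for these genes. A developmental change common to the tissues stays open, as untested.

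The low count of 90 in wing disc (15, 25 and 14 without its replicate 1, 2 or 3) was set against a spread shared with noisier tissues: the median replicate SD was 0.222 in wing disc, 0.715 of the 0.31 over the 4 tissues with 3 replicates, and array weights raised the count 9.51 times, to 856, with all 90 among them. The weights of wing disc replicates 1, 2 and 3 were 3.51, 3.76 and 0.77, so weighting also discounted replicate 3 within the tissue. The rise to 856 therefore does not single out the shared spread. A separate fit, with no shared spread but fewer degrees of freedom, went the other way and gave 49. Compression of ratios that differs between arrays would separate the 2 arrays of wing disc sample 1, on which called genes had median absolute values of 1.34 and 1.03, a ratio of 1.31, and all named features had SDs of 0.549 and 0.296. The ratio lies between the bounds set for and against compression and the SDs include noise, so compression cannot be told apart from noise, as only 1 sample was hybridised on 2 arrays. How much of the low count the shared spread explains therefore stays open, as does a smaller response of the wing disc, as untested.

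These results stood out as differences between tissues. The change between times differed between tissues by limma's F-test for 2064 of 8698 genes, and 1 of 100 splits of the replicates, the real one, gave as many, with 16 in the highest other. Against the mean of the other tissues the counts were 826 in epidermis, 1459 in salivary gland, 396 in wing disc and 974 in midgut, each reached by 1 of 100 splits, with 1, 3, 10 and 1 in the highest other. These 5 counts were thus above those of all other splits drawn. Splits that mix tissues add the differences between tissues to the spread, which lowers their counts. They also cannot address effects of arrays that go with a tissue. The count was 48 in the nervous system, which with 2 replicates was not set against splits. Without 1 replicate the counts were 540 in epidermis without its replicate 3, 454 in midgut without its replicate 3, and 105, 130 and 60 in wing disc without its replicate 1, 2 or 3. For wing disc they were 615 without salivary gland replicate 4 and 250 without nervous system replicate 3. For the nervous system limma gave 0 (339 at an unadjusted p under 0.05) and 383 without its replicate 3 or 4, 84 without salivary gland replicate 4, and 21, 20 and 26 without wing disc replicate 1, 2 or 3.

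The total of 5099 calls was reached by 1 of 100 sign patterns, the real one. The highest other gave 4498, since patterns that turn whole tissues keep their calls. Single tissues have 4 sign patterns, too few for a share under 0.05, of which 1 reached the counts of 1652 in epidermis, 2137 in salivary gland, 90 in wing disc and 1213 in midgut, with 0, 0, 0 and 1 calls in the highest other.

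The largest F values between tissues were 257 for Tsf3, 254 for Miga, 167 for isoQC, 157 for Qsox1, 157 for anchor, 133 for CG1213, 132 for CG11349, 124 for yellow-d2, 123 for Zip99C (188 without salivary gland replicate 4) and 121 for Pex3. Among the genes named by the rule, the largest differences in log2 ratio between epidermis and the mean of the other tissues were 5.32 for speck, 5.17 for ple, 4.83 for Ilp8, -5.07 for yellow-d2, -4.98 for Pxd and -4.89 for Cpr67B. In salivary gland they were 6.09 for Qsox1, 5.69 for Zip99C, 5.56 for Tsf3, -4.68 for ng3, -4.52 for Sgs5 and -4.50 for Eig71Ee. In wing disc they were 2.32 for MFS9, 2.25 for sm, 2.24 for Argk1, -3.33 for CREG, -2.94 for Ctl2 and -2.22 for Tpr2, and the MFS9 call ended without wing disc replicate 1, 2 or 3 (adjusted p = 0.054, 0.0546 and 0.0883). In midgut they were 3.69 for GstE3, 3.65 for Agpat2, 3.38 for Alp1, -4.14 for LysS, -3.98 for PGRP-SC2 and -3.84 for Jon25Biii. In the nervous system they were 1.61 for Cyp4ac1, 1.49 for Pbgs, 1.46 for Ndae1, -2.87 for LManI, -2.64 for CAH1 and -2.10 for ple, and these 6 calls ended without nervous system replicate 3 (adjusted p from 0.339 to 0.803), that of Ndae1 also without replicate 4 (0.0613). A dye term ended the call of Cyp4ac1 (0.0699), and the dye-swapped array as deposited those of MFS9 (0.225) and CREG (0.0838) in wing disc and Ndae1 (0.0801) and CAH1 (0.456) in the nervous system.

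Gene lists differed between a tissue and the others in 33 of 125 tests with the preset correlation and in 1, muscle sarcomere genes in epidermis (adjusted p = 0.0197), with an estimated correlation. A signal was also present in features without a named gene, which were not among the genes compared. Limma called 210 of 7582 in epidermis (141 higher), 278 of 6922 in salivary gland (161 higher), 22 of 4473 in wing disc (20 higher) and 204 of 4600 in midgut (164 higher). In the nervous system limma called 0 of 5219 such features, with 374 at an unadjusted p under 0.05.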

How the results depend on the processing

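The 2 settings that include the dye-swapped array without a dye term were chosen after the data had been seen. Counts stayed within 1.5 times under no centring, single features, fewer required values, a robust prior and either array of wing disc sample 1. The opposite sign of the dye-swapped array has no single value, as its rule left it out, and both signs were run. Camera takes no robust prior, and single features, a separate fit, fewer required values and the minimum change gave no list values. The table holds no intensities, so what signal over background limits cannot be given, and the cause of each shift below was not tested.

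With arrays scaled, the counts were 586 in wing disc and 218 in the nervous system, and 771 and 147 against other tissues. With array weights they were 856 and 23, and 1437 and 149, and CREG in wing disc, not called, was 0.16. With a separate fit they were 651 in epidermis, 49 in wing disc, 701 in midgut, 0 in the nervous system by limma (364 at an unadjusted p under 0.05), 2877 in all and 81 in several tissues. With an absolute log2 ratio of at least 1 they were 937 in epidermis, 1116 in salivary gland, 749 in midgut, 2878 in all, 893 and 608 in salivary gland and midgut against other tissues, and 91 in several tissues. In the nervous system, alone and against other tissues, they were 29 and 108 with a dye term (Eip78C 0.06), 39 and 200 with the swapped array turned (Eip78C 0.03), and 0 (268 unadjusted) and 177 with it as deposited (Sqor 0.05). With an estimated correlation 1 list was called, and with fry 31.

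Pairing of samples by replicate number was not shown, although weak pairing cannot be excluded. Of 19 same-numbered pairs 3 had an r over 0.1 (from -0.212 to 0.228), with a mean of 0.018, against -0.006 for other pairs. The replicate block gave 40 calls in wing disc, 2 in the nervous system and 2 for the nervous system against other tissues, with uncalled values in the nervous system of 0.20 for Eip78C, -0.24 for Hr3 and 0.04 for Sqor. Under it the list calls of ribosomal proteins in epidermis (adjusted p = 0.256) and nervous system (0.152) and of fat body markers in wing disc (0.131) ended.

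With 1 replicate left out, counts ran from 1046 to 1744 in epidermis, 1447 to 2259 in salivary gland, 14 to 117 in wing disc, 575 to 1315 in midgut, 0 (without its replicate 3, 75 unadjusted) to 508 (without its replicate 4) in the nervous system and 4357 to 5400 in all. They ran from 1685 to 2328 for tissue differences, 112 to 241 for several tissues and 27 to 31 for lists. Against other tissues they ran from 540 to 938 in epidermis, 1071 to 1504 in salivary gland, 60 to 615 in wing disc, 454 to 1043 in midgut and 0 (339 unadjusted) to 383 in the nervous system. A tissue left with 1 sample was assumed to vary like the others. Ribosomal proteins in epidermis had a median of -0.03 without replicate 3 (adjusted p = 0.894). Uncalled values that turned sign ran in salivary gland from -0.06 to 0.28 for Akh and from -0.10 to 0.51 for wrapper, in wing disc from -0.02 to 0.15 for Eip78C and from -0.53 to 0.31 for CREG, in midgut from -0.79 to 0.07 for spo and from -0.73 to 0.04 for Eip78C, and in the nervous system from -0.07 to 0.32 for Cat and from -0.11 to 0.05 for Eip78C.

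Of 29 list calls, scaling ended 3 (ribosomal proteins in epidermis, adjusted p = 0.133, and cytochrome P450 and neuronal markers in the nervous system, 0.0559 each), array weights 2 (ribosomal proteins in epidermis, adjusted p = 0.215, and neuronal markers in the nervous system, 0.0508) and the swapped array as deposited 4 (in the nervous system cytochrome P450, 0.679, ribosomal proteins, 0.392, neuronal markers, 0.174, and proteasome, 0.3). Of 295 named values, 0 called ones changed sign under these alternatives. Calls ended for 24 with scaling, 73 with a separate fit, 10 with weights, 38 with the replicate block and 17 with the swapped array as deposited, 2 with no centring (eater in salivary gland, 0.0626, and ImpE1 in wing disc, 0.0528) and 0 with fewer required values or a robust prior. With wing disc sample 1 by its second array 7 of 28 wing disc values lost their call (Osi2, Col4a1, Mcm5, ImpE1, Cht5, Cat and Sqor, adjusted p from 0.0548 to 0.105). Of 40 gene differences between tissues, 34 kept their side of the threshold with the block (the 6 lost were all those of the nervous system, 0.0626 to 0.122), 39 with a dye term, 36 with the swapped array as deposited and 40 under the other settings that leave out no replicate.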

Other observations

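The tests of glycolysis genes and of symbol families were chosen only after results had been seen. The glycolysis list was written after the nervous system calls, which include its member Pglym78, had been seen. Its values in the nervous system are therefore no independent test. Pglym78 was also called lower in epidermis, salivary gland and midgut, so those tissues give no independent test either. Of 14 genes of glycolysis and glycogen breakdown, 10 were measured, and all 10 fell in epidermis (median -2.47, camera, adjusted over the 5 tissues, p = 2.92e-14, and an adjusted p of 0.0134 with an estimated correlation). Glycogen phosphorylase (Glyp) was at -4.18 ± 0.70 there, Gapdh1 at -2.88 ± 0.92, triose phosphate isomerase (Tpi) at -2.81 ± 1.05 and enolase (Eno) at -2.66 ± 0.52 (n = 3). Muscle sarcomere genes also fell in that tissue (median -1.74, 14 of 18 lower), as did Argk1 (-3.66) and SERCA (-2.31), and whether the glycolysis genes fell apart from the muscle genes was not tested. In salivary gland 8 of 10 fell, with a median of -1.15 and Ald1 at -2.55 ± 0.21 (adjusted p = 7.53e-06, and an adjusted p of 0.098 with an estimated correlation). In midgut 3 of 10 fell, with a median of -0.51 (adjusted p = 0.00727, and an adjusted p of 0.283 with an estimated correlation). In the nervous system the median was -1.21 and 1 of 10 fell, or 5 with the dye-swapped array turned (adjusted p = 1.65e-16, and an adjusted p of 0.0134 with an estimated correlation). In wing disc the median was -0.16, and limma called 0 of 10, with 1 at an unadjusted p under 0.05 (adjusted p = 0.0379 for the list, and an adjusted p of 0.353 with an estimated correlation).

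Families of genes that share the letters of their symbol were tested where at least 8 had values. Of 295 tests over 59 families, camera called 43 with the preset correlation and 0 with an estimated correlation, where 22 had an unadjusted p under 0.05. In salivary gland 8 of 10 Alg genes, whose products build the sugar chain of N-glycans, fell, including Alg12 (-2.40 ± 0.63) and Alg3 (-2.19 ± 0.34), with a median of -1.39 (adjusted p = 2.27e-05, and an adjusted p of 0.637 with an estimated correlation). Also in salivary gland 9 of 19 nucleoporin genes (Nup) fell, including Nup50 at -1.65 ± 0.21 (adjusted p = 0.00131, and an adjusted p of 0.637 with an estimated correlation). Of 40 mRpL genes, for the large subunit of the mitochondrial ribosome, 14 fell there (adjusted p = 0.000661, and an adjusted p of 0.693 with an estimated correlation), whereas in midgut 4 of 41 rose and none fell, with a median of 0.27 (adjusted p = 0.0108, and an adjusted p of 0.804 with an estimated correlation). The mRpL list was also lower in wing disc (median -0.20, 1 of 41 lower, adjusted p = 0.000141, and an adjusted p of 0.637 with an estimated correlation) and epidermis (median -0.21, 5 of 39 lower, adjusted p = 0.0482, and an adjusted p of 0.87 with an estimated correlation). In epidermis 7 of 11 GstD glutathione transferase genes fell, including GstD1 and GstD8 (both -1.71), with a median of -0.97 (adjusted p = 0.000661, and an adjusted p of 0.693 with an estimated correlation), whereas in midgut 3 of 11 rose, including GstD1 (0.82 ± 0.26), and none fell, with a median of 0.28 (adjusted p = 0.0697). GstD1 (-1.46 ± 0.47), GstD2 (-1.15 ± 0.98) and GstD8 (-1.1 ± 0.5) also fell in salivary gland. Of 52 Cpr cuticle protein genes in epidermis 12 fell and 3 rose, among them Cpr67Fa1 (-4.16 ± 0.66) and Cpr97Ea (2.46 ± 0.43) (adjusted p = 0.0249, and an adjusted p of 0.771 with an estimated correlation).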
